A study of Homo sapiens with 2 samples.

How the data were processed

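The RNA and ATAC libraries analysed here come from 1 capture of 5 human lines of lung adenocarcinoma (A549, H838, H1975, H2228 and HCC827), grown separately, frozen and mixed in equal parts. Per the labels' protocols, a single capture tube was split into fractions of 80% and 20%. The RNA and ATAC libraries of the 80% fraction are analysed here. The 20% fraction and any long reads are not analysed here. Each barcode carries both an RNA and an ATAC profile, so the same droplets were measured in both ways. There is 1 library of each kind and 1 culture per line, so no test, p-value or standard error was made from barcodes.

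Per the file headers and the submitters' processing notes, the authors made 1 joint matrix of gene and peak counts with Cell Ranger ARC 2.0.0 on GRCh38. Per the labels' protocols, the RNA library was sequenced in 2 runs on a NextSeq 500. The deposited gene counts are whole numbers of unique molecular identifiers (UMIs) per gene and barcode, with no normalisation. The deposited peak counts are whole numbers per peak and barcode, and 83.3% of the non-zero entries are even, with 61.5% equal to 2. A fragment therefore usually adds 2 counts, and counting intervals of peaks were computed on counts divided by 2. The other deposited values, used only as positions, are the start and end of each gene or peak per the file headers. Gene entries span annotated transcription starts rather than gene bodies and carry no strand, and the 13 mitochondrial genes have no position. How barcodes were called as cells, how peaks were called, which gene annotation was used and whether RNA counting used strand are not given in the sources used here. Antisense genes therefore cannot be told apart from their sense partners. Near-identical families (AKR1C1 with AKR1C2 and AKR1C3, SAA1 with SAA2, the MAGE-A, GAGE, PSG, HLA and metallothionein genes) may share reads and are uncertain to that extent.

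Barcodes were kept with at least 1000 UMIs, at least 500 genes, at least 1000 peak counts and at most 20% mitochondrial UMIs. Of 3298 barcodes, 494 were left out and 2804 kept. The mitochondrial limit applied to 378 barcodes, the UMI minimum to 62, the gene minimum to 43 and the peak count minimum to 76, with some barcodes under several. Doublets were scored with Scrublet in scanpy 1.11.5, and the 63 highest scores were removed, at the expected 0.8% per 1000 barcodes, which left 2741. The automatic Scrublet threshold called only 6 barcodes (0.214%).

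RNA counts were scaled to the median total and log-transformed. The 2000 most variable genes, 30 principal components and 20 neighbours entered Leiden clustering. ATAC counts of peaks seen in at least 1% of barcodes were weighted by TF-IDF and reduced to 30 components. The first component correlated with depth at r = 0.990 and was left out, and 20 neighbours entered Leiden clustering. In each library the lowest resolution that gave at least 5 clusters of at least 1% of barcodes was used, which was 0.1 in both. RNA and ATAC clusters were matched by the Hungarian method, and a number stands for the same cluster in both libraries. A cluster was called after a line only where markers fixed before the data were examined settled it.

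Genes were compared between ATAC clusters and peaks between RNA clusters, so that no feature defined the clusters it was compared between. UMIs or peak counts were summed per cluster and expressed as CPM, scaled to the cluster's total. Log2 ratios are of CPM + 1 against the mean CPM of the other clusters + 1, which understates ratios of low genes. A gene very high in 1 cluster raises that mean, and can then count as lower in all the others. Genes with at least 20 UMIs (20959) and peaks with at least 100 counts (133185) were taken as measured. A list member was counted as higher or lower at 2-fold, and a peak as leading at 4-fold. The median of each gene list was placed among 10000 random lists of the same size matched on mean expression. Factors from trimmed means (TMM, edgeR 4.0.16, R 4.3.3) served as an alternative scaling and moved the median log2 ratio of all genes by up to 0.18. Intervals are exact Poisson for sums and exact binomial (Clopper-Pearson) for shares, at 95%, and cover counting error only.

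The gene lists, fixed before the data were examined, were NRF2 targets, epithelial, mesenchymal, lung lineage, gastro-hepatic lineage, MHC class I, MHC class II, interferon-stimulated, S phase, G2/M phase, MAPK output, YAP/TEAD targets, cancer-testis antigens, metallothioneins, hypoxia and glycolysis, acute phase and chemokines, drivers and tumour suppressors, and markers of immune, endothelial, fibroblast and red cells. The NRF2 list holds all H838 markers, and the lung lineage, gastro-hepatic, MHC class II, acute phase and driver lists share members with the line markers, so they are not independent of the cluster names. Genes named in the text are, for each cluster, the 5 with the largest ratio of CPM + 1 to the highest other cluster among genes with at least 100 UMIs, without clone-based names, XIST and Y-linked genes. To these were added the 4 members of each list with the largest absolute log2 ratio, the drivers and the line markers. TSIX met the rule in cluster 4 and is not reported here, and neither are some list members, drivers and loci that met the rules. Other list members and the neighbours of EGFR named were chosen after their values were seen. Named peaks are the 2 with the largest such ratio per cluster among peaks with at least 200 counts.

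Promoter accessibility was the sum of peaks within 2000 bases of the gene's start span, for genes measured and with at least 100 promoter counts. Pearson and Spearman correlations were taken across genes, which are not independent replicates. They used barcodes in matched clusters of both kinds, so genes and peaks both helped to choose those barcodes. Dosage was the share of peak counts per chromosome, per 5 Mb window with at least 20 measured peaks and within 500 kb of 15 loci fixed beforehand, each against the mean of the other clusters. The EGFR locus in cluster 4 and the CDKN2A locus in cluster 1 were followed through the alternatives, and were picked for this after marker values had been seen.

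After the data had been seen, each barcode's RNA and ATAC profile was also fitted by non-negative least squares as a mixture of the 5 cluster profiles (300 genes and 3000 peaks per cluster). A barcode was called mixed where its largest weight was under 0.7 in either library, and "mixed barcodes left out" below refers to this choice. The fit used genes and peaks chosen for being high in 1 cluster. Leaving out mixed barcodes therefore selects partly on features then compared, which can enlarge ratios. For those values the separation of genes and peaks between libraries does not hold.

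The steps were tested on simulated data made from the real profiles. Clustering of 1000 simulated barcodes, each drawn from 1 cluster profile at a real depth, gave an adjusted Rand index of 1 in both libraries. These held no mixed barcodes and no spread between cells of a cluster, so the index does not bear on the agreement in the real data. With 200 changed features per cluster, 100% of genes simulated at 4-fold and at 8-fold passed 2-fold, and 100% of peaks simulated at 8-fold and at 16-fold passed 4-fold. Among unchanged genes at most 0.00965% passed, and 0% of unchanged peaks did. Counts held Poisson error only, and changed features had at least 100 UMIs or 200 counts. Changes nearer the thresholds and features nearer the minimum counts were not simulated. Of 1000 pairs of real barcodes summed into 1, the mixture fit found 30.4% as mixed in both libraries, and 92.1% of the 151 pairs of even depth. Among those found, it named the right pair in 93.8%, so most simulated pairs of uneven depth were missed.

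Alternatives covered the cell filter, doublet removal, clustering, components, ATAC weighting and features, depth, scaling, pseudocount, minimum counts, thresholds, promoter windows and locus windows. Binarised peaks used a minimum of 50 barcodes. The gene-body alternative used the whole span of starts plus 2000 bases on either side, since no strand was available. Motifs in peaks were not analysed here, since no genome sequence was used. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 were used.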

Results

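The mixture of lung adenocarcinoma lines was profiled as a reference for methods of single-cell ATAC analysis. A549, H838, H1975, H2228 and HCC827 are established lines; HCC827 carries an amplified EGFR gene, H2228 an EML4-ALK fusion, and A549 and H838 carry KEAP1 mutations. The joint matrix held 3298 barcodes, 36601 genes, of which 5997 had no UMI, and 187920 peaks with a median width of 881 bases. Of the peaks, 27623 lay within 2000 bases of a gene start and 160297 were distal. The RNA library held 62477861 UMIs and the ATAC library 131221183 peak counts. Barcodes had medians of 9870 UMIs, 4044.5 genes, 22632 peak counts and 7.34% mitochondrial UMIs. The 2741 barcodes kept had medians of 8842 UMIs, 3900 genes, 23560 peak counts and 3.54% mitochondrial UMIs, and totals of 45930854 UMIs and 104697335 peak counts. Each library was made once, so all values below lack replicates and their intervals cover counting error only.

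With the resolution set to give 5 clusters in each library, the RNA and ATAC clusters matched closely. No line labels were used, so this is agreement between the libraries and does not measure recovery of the mixed lines. Clusters 1, 3 and 4 matched almost completely: 749 of the 749 barcodes of RNA cluster 1, 592 of the 599 of RNA cluster 3 and 434 of the 447 of RNA cluster 4 lay in the ATAC cluster of the same number. RNA cluster 5 matched in 243 of 244 barcodes. RNA cluster 2 was the exception, with 511 of its 702 barcodes in ATAC cluster 2 and 160 in ATAC cluster 5. In all, 2529 of 2741 barcodes (92.3%, interval 91.2% to 93.2%) were in matched clusters, with an adjusted Rand index of 0.857 and an adjusted mutual information of 0.862. Of the 212 unmatched barcodes, 201 (94.8%) were called mixed, a call that rests on the same cluster profiles and so tends to pick barcodes between clusters. Leiden clustering at resolution 0.5, which gave 9 RNA and 8 ATAC clusters, lowered the matched share to 69.1%.

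**Figure D1:**
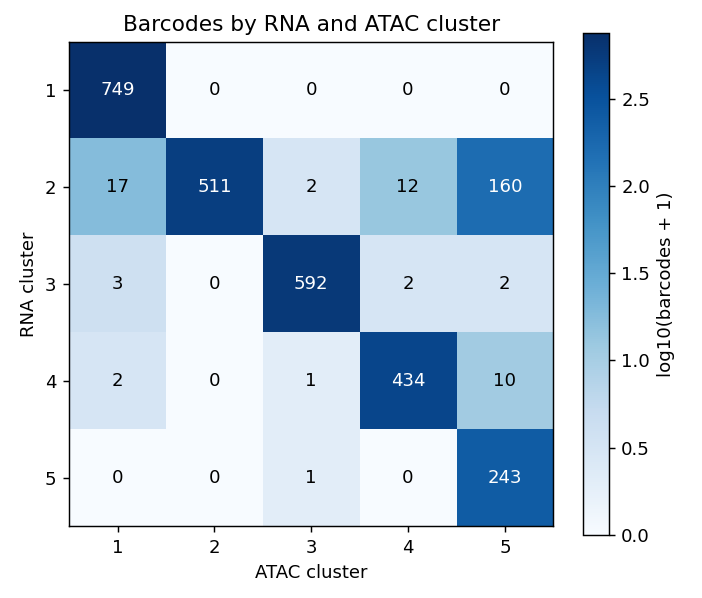
Number of barcodes in each combination of RNA cluster (vertical axis) and ATAC cluster (horizontal axis); shading is log10 of barcodes + 1. Matched clusters on the diagonal hold 749, 511, 592, 434 and 243 barcodes, and the 160 barcodes of RNA cluster 2 and ATAC cluster 5 form the largest group off it.

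The clusters were of unequal size, although the lines had been mixed in equal parts (20% each). By RNA, cluster 1 held 27.3% of barcodes (25.7% to 29.0%), cluster 2 25.6% (24.0% to 27.3%), cluster 3 21.9% (20.3% to 23.4%), cluster 4 16.3% (14.9% to 17.7%) and cluster 5 8.90% (7.86% to 10.0%). By ATAC, cluster 2 held 18.6% and cluster 5 15.1%, while clusters 1, 3 and 4 held 28.1%, 21.7% and 16.3%. Clustered with no filter, cluster 2 held 15.1%, cluster 4 19.9% and cluster 5 18.0%, and 30.3% of barcodes in cluster 4 and 18.0% of those in cluster 5 exceeded 20% mitochondrial UMIs. The RNA resolution that gave 5 clusters was then 0.15, and cluster 2 held 486 barcodes in place of 702 and cluster 5 579 in place of 244, so the filter is not the only difference between these shares.

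Cluster 1 was A549-like, with all 7 A549 markers highest in it. ALDH1A1, a retinaldehyde dehydrogenase, reached 2645 CPM, and CYP24A1, which inactivates vitamin D, 1459 CPM. CPS1, the first enzyme of the urea cycle, reached 149 CPM, the mucin gene MUC5AC 119 CPM, and the fibrinogen genes FGB, FGG and FGA 130, 96.7 and 96.4 CPM. Cluster 4 was HCC827-like, with 5 of the 6 HCC827 markers highest in it: EGFR at 7703 CPM (7636 to 7770), its neighbours VOPP1 at 1626, LANCL2 at 664 and SEC61G at 557 CPM, and CEACAM5 at 16.7 CPM. EGFR and these neighbours lie in the same stretch of chromosome 7, so they are not independent markers. CEACAM6 was at 41.7 CPM in cluster 1 and 25.2 in cluster 4, and was highest in cluster 4 (27.1 CPM) once mixed barcodes were left out. The H1975 markers NKX2-1 (92.3 CPM), SFTA3 (149 CPM) and SFTPB (3.16 CPM) were also highest in cluster 4. Of the other H1975 markers, VIM was highest in cluster 2 (857 CPM) and CD274 in cluster 5 (24.7 CPM). Cluster 2 had the highest level of 4 of 6 H2228 markers, LCN2 (9506 CPM), CD74 (2168 CPM), SAA1 (942 CPM) and SAA2 (292 CPM). ALK, however, was at 15.87 CPM in cluster 2 and 15.97 CPM in cluster 4, and CDKN2A was at 18.5 CPM in cluster 2 and 309 CPM in cluster 4. Of the 9 H838 markers, 7 were highest in cluster 1, and ALDH3A1 (219 CPM) and SRXN1 (42.3 CPM) in cluster 2. The markers thus did not settle clusters 2, 3 and 5, which stay numbered.

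Cluster 1 combined NRF2 target expression with genes of the liver and gut lineage and low epithelial and antigen presentation genes. Of 29 NRF2 targets, which respond to oxidative stress, 18 were higher and 0 lower than in the other clusters, with a median log2 ratio of 1.21. AKR1C2 reached 1503 CPM, AKR1C1 894 CPM and AKR1B10 732 CPM (709 to 755), against 18.4 CPM of AKR1B10 in cluster 4 and 8.08 CPM in cluster 3. Of 16 measured gastro-hepatic genes, 11 were higher and 1 lower (median 2.57), among them the hepatic regulator HNF4A at 50.8 CPM (44.9 to 57.2). The epithelial list was lower in 17 of 23 members (median -2.25), MHC class I in 12 of 12 (median -1.70), MHC class II in 9 of 10 (median -2.33) and the interferon-stimulated list in 14 of 21 (median -1.23). Low MHC class I was not particular to cluster 1. HLA-B, HLA-C, HLA-F and PSMB9 were lower still in cluster 3, HLA-B at 59.1 CPM against 130 CPM in cluster 1. Cluster 2, with HLA-B at 1443 CPM, raises the mean of the others. Of 22 mesenchymal genes, 11 were lower and only N-cadherin (CDH2, 103 CPM against at most 5.42 elsewhere) was higher. The 5 leading genes were CPLX2 (ENSG00000145920, chromosome 5, 175796310 to 175878206) at 163 CPM (153 to 174) against at most 3.33 CPM elsewhere, RBFOX3 at 396 CPM, LINC02506 at 312 CPM, IGSF11 at 253 CPM and GPRIN3 at 246 CPM. CPLX2 encodes a complexin of synaptic vesicles and RBFOX3 a neuronal splicing factor.

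Cluster 2 had the highest expression of secreted inflammatory genes and of antigen presentation genes, with low proliferation genes. All 18 acute phase and chemokine genes were higher (median 2.58), including CCL20 at 301 CPM, the immunoglobulin receptor PIGR at 248 CPM, CXCL6 at 145 CPM and CXCL5 at 143 CPM. All 10 MHC class II genes were higher (median 3.23), with HLA-DRB1 at 846 CPM (829 to 863), HLA-DQA1 at 205 CPM and HLA-DQB1 at 165 CPM. MHC class I was higher in 9 of 12 (median 1.73), with HLA-B at 1443 CPM and HLA-C at 1021 CPM. Both medians were larger with mixed barcodes left out, at 4.24 for MHC class II and 2.04 for MHC class I, a rise that the choice of these barcodes may partly fix. Among 50 G2/M genes 42 were lower and 0 higher (median -1.67), and among 39 S phase genes 18 were lower and 0 higher (median -0.82). By RNA clusters the lower genes numbered 28 in G2/M (median -1.06) and 8 in S phase (median -0.58). The mitotic genes BUB1 and AURKB were at 10.6 and 9.05 CPM, against 101 and 65.8 CPM in cluster 3. MAPK output genes were higher in 6 of 17 (median 0.83), with the phosphatase DUSP6 at 109 CPM. The leading genes were LINC02755 (ENSG00000254530, chromosome 11, 29594350 to 29989328) at 82.3 CPM (77.1 to 87.7), the calprotectin subunit S100A9 at 457 CPM, the cystatin CST1 at 101 CPM, ATP10B at 24.6 CPM and BMP3 at 12.6 CPM.

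Cluster 3 was marked by cancer-testis antigens and proliferation genes and by low epithelial and lung lineage genes. Of 16 measured cancer-testis genes, normally restricted to germ cells, 13 were higher and 1 lower (median 3.07), with MAGEA10 at 127 CPM (118 to 136), MAGEA4 at 43.1 CPM, CTAG2 at 32.1 CPM and MAGEA1 at 30.6 CPM. MAGEA10 was at most 6.06 CPM elsewhere. Epithelial genes were lower in 21 of 23 (median -3.00), with ESRP1, an epithelial splicing regulator, at 4.81 CPM and GRHL2 at 6.87 CPM. Lung lineage genes were lower in 11 of 14 (median -2.50), MHC class II in 10 of 10 (median -3.18), interferon-stimulated genes in 17 of 21 (median -1.35) and MAPK output in 11 of 17 with 0 higher. The growth factors EREG and AREG were at 12.4 and 18.7 CPM, against 361 and 305 CPM in cluster 4. G2/M genes were higher in 18 of 50 (median 0.84; 11 by RNA clusters) and S phase genes in 16 of 39 (median 0.75), EXO1 reaching 93.0 CPM. Mesenchymal genes went both ways, with 6 higher and 8 lower, THY1 at 18.4 CPM and MMP2 at 1.20 CPM. The leading genes were LINC01194 at 413 CPM, the zinc transporter gene SLC30A8 at 323 CPM, GRM7-AS3 at 81.6 CPM, GNAS-AS1 at 65.5 CPM and the serotonin receptor gene HTR1E (ENSG00000168830, chromosome 6, 86937528) at 53.3 CPM (47.5 to 59.5).

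Cluster 4 had the highest epithelial and lung lineage expression, with low mesenchymal genes and NRF2 targets. Epithelial genes were higher in 16 of 23 and lower in 0 (median 1.85), with EPCAM at 688 CPM, GRHL2 at 242 CPM (230 to 254) and ESRP1 at 211 CPM (200 to 222). Lung lineage genes were higher in 8 of 14 and lower in 2 (median 1.66), including SFTA2 at 52.7 CPM and NKX2-1, a lung transcription factor, at 92.3 CPM (85.2 to 100.0). Mesenchymal genes were lower in 14 of 22 (median -1.80), NRF2 targets in 26 of 29 (median -1.80), MHC class II in 10 of 10 (median -2.92) and S phase genes in 11 of 39 (median -0.71). Low MHC class II was shared with clusters 1 and 3, since cluster 2 raises the mean of the others. CD74 was at 86.9 CPM in cluster 4, against 122 and 64.3 CPM in clusters 1 and 3 and 2168 CPM in cluster 2. Interferon-stimulated genes were higher in 5 of 21 (median 0.43; 8 by RNA clusters), IFI44L reaching 80.4 CPM. The leading genes were the glutamate receptor gene GRIA4 (ENSG00000152578, chromosome 11, 105610029 to 105610998) at 135 CPM (126 to 144), LINC01980 at 112 CPM, LINC01456 at 99.0 CPM and the hormone precursor gene PMCH at 32.2 CPM.

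In cluster 5 mesenchymal genes were more often higher than lower. Of 22 mesenchymal genes 10 were higher and 5 lower (median 0.58; 3 lower with TMM), with TGFBI at 1344 CPM and the collagen gene COL5A1 at 322 CPM (313 to 331). The 160 barcodes of RNA cluster 2 held 75.1% of the UMIs of ATAC cluster 5, so its values lie between those of both clusters. With mixed barcodes left out, TGFBI and COL5A1 were at 1487 and 425 CPM, and 19 of 29 NRF2 targets were lower in place of 10, 8 of 10 MHC class II genes in place of 0 and 13 of 18 acute phase and chemokine genes in place of 0. For the latter 2 lists the mean of the other clusters is raised by cluster 2, so lower does not mean that cluster 5 had the lowest levels. The leading genes were DHRS2 at 154 CPM (251 with mixed barcodes left out), NALCN-AS1 at 124 CPM (207), ZNF676 at 93.3 CPM (169), PLK5 (ENSG00000185988, chromosome 19, 1524077 to 1524959) at 55.3 CPM (95.4) and PSG4 at 25.1 CPM (37.7). Interferon-stimulated genes were higher in 4 of 21 (median 0.51), and with mixed barcodes left out in 2, with 1 lower (median 0.31). Of 4 measured fibroblast markers, 3 were higher (median 1.65), COL1A1 at 105 CPM and COL1A2 at 44.2 CPM. COL1A1 was at 108 CPM in cluster 2.

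Markers of cells outside the 5 lines were few. None of the 5 red cell markers was measured, and 4 of 12 immune and 5 of 8 endothelial markers were. PTPRC reached 6.29 CPM in cluster 2, CD14 8.24 CPM in cluster 5, CSF1R 6.06 CPM in cluster 5 and CD79A 2.41 CPM in cluster 4. PECAM1, an endothelial marker, was at 88.4 CPM in cluster 2, while KDR, ERG and EMCN did not exceed 2.06 CPM in any cluster. All lists together had 50, 79, 64, 46 and 26 members higher in clusters 1 to 5. Of the list medians given so far, the positive ones lay at percentile 99.9 or above among random lists of the same expression, and the negative ones at percentile 0.05 or below. Medians by RNA clusters or with mixed barcodes left out were not placed among random lists. Random genes were drawn independently, while members of a list can move together, so these percentiles are not p-values.

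**Figure D2:**
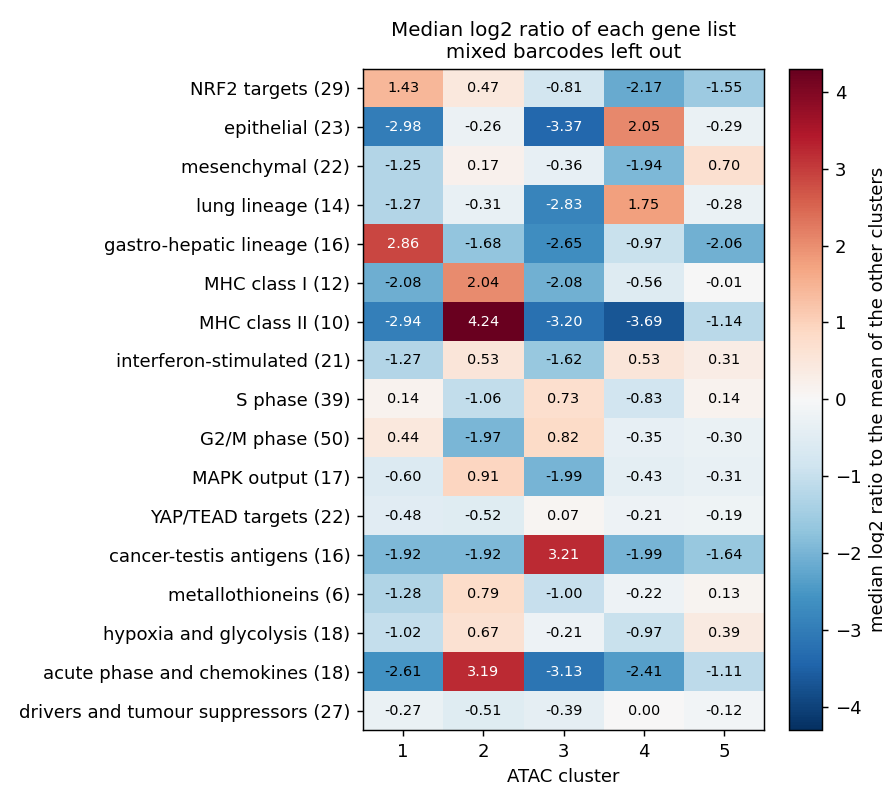
Median log2 ratio of each gene list (rows, measured members in brackets) in each ATAC cluster (columns) against the mean of the other clusters, with mixed barcodes left out; red is higher and blue lower. The largest medians are MHC class II (4.24) and acute phase genes (3.19) in cluster 2, cancer-testis antigens (3.21) in cluster 3 and gastro-hepatic genes (2.86) in cluster 1.

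Among drivers and tumour suppressors, EGFR, CDK4 and the CDKN2A locus differed widely between clusters. CDK4, a cell cycle kinase, was at 450 CPM and the receptor MET at 741 CPM in cluster 4, and MDM2, a ubiquitin ligase, was at 217 CPM in cluster 1. In cluster 4, 8 of 27 measured drivers were higher and 2 lower (median 0.02, or -0.03 by RNA clusters), and with TMM 0 were lower. CDKN2A, which encodes inhibitors of the cell cycle, was at 309 CPM (296 to 323) in cluster 4 and 73.6 CPM in cluster 5, and at 15.4, 18.5 and 6.19 CPM in clusters 1 to 3. With mixed barcodes left out it was at 6.25, 9.08 and 1.28 CPM in clusters 1 to 3, and at 325 and 90.4 CPM in clusters 4 and 5. RB1 ranged from 47.2 CPM in cluster 5 to 171 CPM in cluster 3. ALK did not exceed 15.97 CPM in any cluster, and EML4 was highest in cluster 1 at 658 CPM.

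Accessible regions that differed between the RNA clusters lay mostly away from gene starts, as most peaks do. Leading peaks numbered 2487, 1005, 2502, 2118 and 1666 in clusters 1 to 5, of 133185 measured. The numbers depended on the processing: with TMM they were 3817 in cluster 1 and 642 in cluster 2, by ATAC clusters 1016 in cluster 5 and with binarised counts 1509 in cluster 2. Between 84.9% of them in cluster 2 and 89.8% in cluster 5 were distal, against 81.4% of all measured peaks. At 2-fold, however, the share in cluster 1 was 80.4%, and with no minimum count 85.3% of all peaks were distal, more than the 84.9% in cluster 2. In cluster 1 a peak at the start of GALNT13 (chromosome 2, 153871357 to 153872258) was at 52.1 CPM (47.9 to 56.5) and at most 2.09 CPM elsewhere, and GALNT13 RNA was at 228 CPM in cluster 1 and at most 41.3 CPM elsewhere. In cluster 4 a peak 56926 bases from the start of EGFR (chromosome 7, 54961235 to 54962091) was at 166 CPM (154 to 179). In cluster 5 a peak 8580 bases from the start of PVT1 (chromosome 8, 127803117 to 127803900) was at 31.9 CPM (26.8 to 37.6). A peak on chromosome 20 (11791524 to 11792401), 18025 bases from LINC00687, was at 91.1 CPM (83.8 to 98.8) in cluster 3. In cluster 2 the peak on chromosome 14 (91243217 to 91244121), 282 bases from AL135818.1, was at 27.3 CPM (25.3 to 29.4), and a peak 21104 bases from IKBKB on chromosome 8 (42292406 to 42293312) at 21.6 CPM (19.8 to 23.4). The remaining named peaks were on chromosome 2 (43162689 to 43163609) at 63.8 CPM in cluster 1, chromosome 15 (98899384 to 98900277) at 76.4 CPM in cluster 3, chromosome 7 (54857851 to 54858744) at 49.9 CPM in cluster 4 and chromosome 8 (127684444 to 127684910) at 11.9 CPM in cluster 5. The named peaks of cluster 4 lay within 500 kb of EGFR, where the whole region was 14.3-fold higher in cluster 4. Those of cluster 5 lay within 500 kb of MYC, where the whole region was 5.66-fold higher in cluster 5. These peaks therefore need not differ by their own accessibility, and the numbers of leading peaks were not corrected for such regions. The 160 barcodes held 47.4% of the peak counts of RNA cluster 2, and with mixed barcodes left out cluster 2 had 2678 leading peaks.

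Promoter accessibility and expression were correlated in every cluster. Across 15770 genes, Spearman correlations of the promoter and expression log2 ratios were 0.514, 0.444, 0.600, 0.524 and 0.545 in clusters 1 to 5, a mean of 0.525 ± 0.056 (SD over 5 clusters of 1 library), and Pearson correlations averaged 0.575 ± 0.051. Of the genes at least 2-fold higher in expression, 31.7%, 29.3%, 37.7%, 37.4% and 21.2% also had a promoter at least 2-fold more accessible. Of all 15770 genes, 1112, 902, 1180, 704 and 477 had such a promoter. Gains and losses of a region would move promoter counts and RNA together, and were not separated here. Opposite changes of 2-fold were rarer, in 77, 24, 48, 27 and 29 genes.

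Peak counts along the chromosomes differed between clusters by region, and established lines are known to carry gains and losses. Within 500 kb of EGFR (chromosome 7, 55019017 to 55152337), the ATAC log2 ratio of cluster 4 was 3.84 (3.82 to 3.85), a 14.3-fold share, and EGFR RNA had a log2 ratio of 3.61. The 5 Mb window from 55 to 60 Mb of chromosome 7 was 9.36-fold higher in cluster 4. In cluster 5 the largest window was chromosome 19 from 20 to 25 Mb (4.36-fold) and the smallest chromosome 13 from 65 to 70 Mb (0.232-fold), which in cluster 1 was the largest (2.73-fold). Chromosome 5 from 25 to 30 Mb was the smallest in cluster 3 (0.161-fold). In cluster 1 the smallest was chromosome 16 from 60 to 65 Mb, with an ATAC log2 ratio of -2.45, while the RNA ratio of that window went the other way, at 1.41. Around NKX2-1 the log2 ratio was 1.23 in cluster 4 and -1.93 in cluster 3, and around RB1 it was 0.82 in cluster 3 and -0.96 in cluster 5.

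Around CDKN2A (chromosome 9, 21971332 to 21995301) the ATAC log2 ratio was -4.48 (-4.80 to -4.16) in cluster 3 and -1.61 in cluster 2, or -4.13 in cluster 2 with mixed barcodes left out. In clusters 1, 4 and 5 it was 0.51 (0.46 to 0.56), 1.64 and 0.11, with the TMM scaling giving 0.90 in cluster 1. Over 23 chromosomes, the log2 ratios of RNA and ATAC shares correlated at Pearson r = 0.602, 0.776, 0.943, 0.892 and 0.784 in clusters 1 to 5. RNA shares came from ATAC clusters and ATAC shares from RNA clusters, so for clusters 2 and 5 the barcodes differed in part. With mixed barcodes left out the correlations were 0.589, 0.804, 0.958, 0.898 and 0.865. ATAC peaks depend on regulation as well as on copies, so these ratios are not copy numbers.

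**Figure D3:**
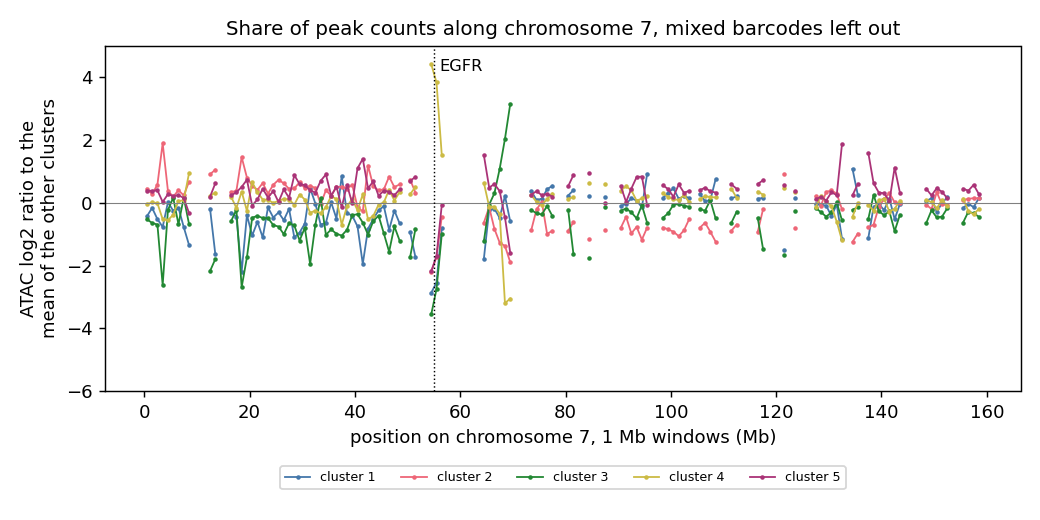
Log2 ratio of each RNA cluster's share of peak counts to the mean of the other clusters (vertical axis) in 1 Mb windows along chromosome 7 (horizontal axis, Mb), with mixed barcodes left out and windows under 20 measured peaks left blank. Cluster 4 stands at 4.42 in the window from 54 to 55 Mb and 3.84 in the next, beside EGFR (dotted line).

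Mitochondrial genes took very different shares of UMIs in the clusters. In matched barcodes that were not mixed, the median share was 0.420% in cluster 1, 8.81% in cluster 2, 0.418% in cluster 3, 13.8% in cluster 4 and 6.06% in cluster 5. Barcodes under 2% made up 89.3%, 8.46%, 68.8%, 19.3% and 46.0% of the clusters. Ribosomal protein genes, whose RNA is cytoplasmic, moved with it, at medians of 1.21%, 5.13%, 1.90%, 3.85% and 2.24% of the other UMIs. In all barcodes of ATAC cluster 5, from which its gene values come, the median mitochondrial share was 12.2%. The gene groups described for clusters 2, 4 and 5 therefore come from barcodes with more mitochondrial RNA than those of clusters 1 and 3.

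**Figure D4:**
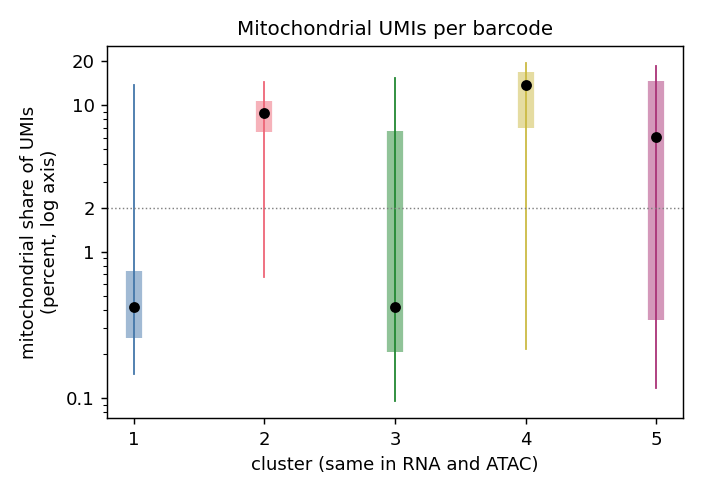
Mitochondrial share of UMIs per barcode (percent, log axis) in each cluster, for barcodes with the same cluster in RNA and ATAC and not mixed; points are medians, bars the middle 50% and lines the 5th to 95th percentiles of barcodes. Medians of clusters 1 and 3 (0.420% and 0.418%) lie under the dotted line at 2%, and those of clusters 2, 4 and 5 (8.81%, 13.8% and 6.06%) above it.

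Most of the 160 barcodes in RNA cluster 2 and ATAC cluster 5 were fitted as mixtures of both clusters, 87.5% being called mixed in RNA and 89.4% in ATAC. Their median of 63904.5 UMIs was 2.61 times the sum of the medians of clusters 2 and 5 (24490), and their median of 117625 peak counts exceeded the corresponding sum of 61068. What raised them above these sums was not tested. Median weights of the cluster 2 and cluster 5 profiles were 0.426 and 0.436 in RNA and 0.433 and 0.461 in ATAC. The fit could only divide a barcode among the 5 cluster profiles. These barcodes were also picked for lying in clusters of different number, so intermediate weights are partly fixed. Among 2804 barcodes that passed the filter, 225 (8.02%) were mixed in both libraries, 193 of them (85.8%) as the same pair, and Scrublet scores had removed 33. The pair of clusters 2 and 5 made up 113 of the 225, or 50.2% (43.5% to 56.9%).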

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

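Leaving out mixed barcodes, and leaving mitochondrial UMIs out of the totals, were chosen after the results had been seen; the other alternatives were fixed before the data were examined. The log2 ratios of the single genes, peaks and loci followed here kept their direction. Some list medians near 0 changed sign, such as MHC class I in cluster 5 (0.35, and -0.11 with matched clusters only) and S phase in cluster 5 (-0.10 and 0.27). Of the main results, 93 comparisons with an alternative stayed within their interval (shares, loci), their spread over clusters (promoters) or 1.5-fold (counts), and 49 moved. Of the single genes and peaks named, 104 stayed and 156 moved. The cause was not tested for any of these moves, except where more clusters or another threshold follow from the alternative itself.

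The matched share of 92.3% became 88.8% with no cell filter, 96.1% with the stricter filter, 95.8% with k-means, 69.1% with Leiden at resolution 0.5, 96.6% with 50 components, 96.8% with binarised ATAC counts, 91.0% with log TF times log IDF, 97.3% with the first component kept, 96.8% with promoter peaks only and 99.5% with mixed barcodes left out, a rise that the definition of mixed partly fixes. At lower depth it was 93.4% with ATAC thinned to 10%, 87.0% with ATAC thinned to 2% and 82.9% with RNA thinned to 10%. The resolution giving 5 clusters also rose to 0.15 with no filter, with binarised counts, with ATAC thinned to 2% and with RNA thinned to 10%. The 19 alternatives fixed beforehand gave adjusted Rand indices of 0.656 to 0.942.

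With no cell filter, the shares of clusters 1, 2, 4 and 5 became 25.3%, 15.1%, 19.9% and 18.0%. By ATAC clusters, cluster 2 held 18.6% and cluster 5 15.1%, and by k-means 21.6% and 12.0%. With mixed barcodes left out, clusters 1, 2 and 3 held 30.2%, 19.3% and 23.9%. A pseudocount of 10 CPM lowered the higher list members to 34 in cluster 3 and 13 in cluster 5.

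Leading peaks numbered 9977, 12009, 9999, 12116 and 16199 in clusters 1 to 5 at 2-fold and 442, 45, 630, 260 and 45 at 8-fold. With TMM they were 3817 in cluster 1 and 642 in cluster 2, with binarised counts 1509 in cluster 2, with mixed barcodes left out 2678 in cluster 2, and by ATAC clusters 1016 in cluster 5. The log2 ratio around EGFR in cluster 4 (3.84) became 3.86 with TMM, 3.43 within 1 Mb, 3.87 with distal peaks and 4.18 with mixed barcodes left out. Around CDKN2A in cluster 1 (0.51) it became 0.90, 0.62, 0.71 and 0.64 in the same order. The mean promoter correlation stayed within its spread under every window and minimum tried. Motifs in leading peaks, with their alternatives, were not run. No paired analysis was possible because each library was made once.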

Other observations

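The tests of free mitochondrial RNA and of kept cytoplasm were written before their results were seen, and all other tests here were chosen after the result was seen. At chromosome 9, the neighbouring genes CDKN2A, CDKN2B and MTAP, a methionine salvage enzyme, parted in cluster 1. With mixed barcodes left out, MTAP was at 109 CPM with 37.4 CPM of promoter peaks there, while CDKN2A was at 6.25 CPM and CDKN2B at 0.463 CPM, with promoter peaks of 0.659 and 0.141 CPM. In clusters 2 and 3 all of them were low, MTAP at 8.77 and 1.1 CPM with promoter peaks of 0.930 and 0.336 CPM. Cluster 4 had 325 CPM of CDKN2A, 55.3 CPM of CDKN2B and 346 CPM of MTAP, and cluster 5 90.4, 19.2 and 129 CPM. Around MYC on chromosome 8 the ATAC log2 ratio of cluster 5 was 2.50, and 3.02 with mixed barcodes left out. PVT1 RNA was highest in cluster 5 at 1903 CPM, but MYC RNA was no higher there than in cluster 4. It was at 82.5 CPM in cluster 5 and 113 CPM in cluster 4 (105 to 121), or 98.7 and 106 CPM with mixed barcodes left out.

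Of 22 YAP/TEAD targets, at most 4 were higher and at most 6 lower in any cluster, with medians from -0.45 to 0.13 that changed sign with TMM in clusters 3, 4 and 5 and by RNA clusters in cluster 3. Single members still differed widely: IGFBP3 was at 2136 CPM in cluster 2 and 33.8 CPM in cluster 3, the coagulation factor gene F3 at 534 CPM in cluster 4 and 29.0 CPM in cluster 1, and CCN1 at 533 and 39.6 CPM in the same clusters. Hypoxia and glycolysis genes were higher in 4 of 18 in cluster 2 (median 0.64), with VEGFA at 269 CPM and the carbonic anhydrase CA9 at 49.1 CPM, and lower in 9 of 18 in cluster 4, with CA9 at 1.81 CPM. Of 6 metallothioneins measured, 5 were lower in cluster 1 (median -1.29), MT1E at 3.16 CPM, and 2 were higher in cluster 2 (median 0.62). ROS1, a receptor kinase, was at 53.2 CPM in cluster 2 and 3.61 CPM in cluster 3.

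Around EGFR, in matched barcodes that were not mixed, 122 of 130 peaks with at least 100 counts there (93.8%, 88.2% to 97.3%) were at least 4-fold higher in cluster 4, as more copies would give, against 2.14% of all 102625 such peaks. The neighbours SEC61G, LANCL2 and VOPP1 had a median log2 ratio of 3.26, which argues against regulation of EGFR alone. They are also HCC827 markers that helped to name cluster 4, so this outcome was known when the test was chosen. With TMM the ratio of the region was 3.86. The TMM factors of peaks ran only from 0.810 to 1.13 over the clusters, too little to move such a ratio far, so this did not test scaling. Further away the RNA log2 ratios were 2.26 at LINC01446, -0.35 at COBL and -0.10 at GRB10 on one side, and 1.98 at ZNF713, 1.19 at PSPH and 1.35 at CHCHD2 on the other. A candidate explanation is amplification of this stretch of chromosome 7, which is known in HCC827, although the peaks cannot count copies. Cluster 4 was called HCC827-like mostly from genes of this stretch, so its name is not separate support. The design gives no groups of samples, so no biological difference between groups was tested.

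The 160 barcodes of RNA cluster 2 and ATAC cluster 5 may hold cells of both clusters. Peaks at the starts of CDKN2A, CDKN2B and MTAP lay at 32.7 CPM in them, 0.511 of the way (0.460 to 0.566) from cluster 2 (1.84 CPM) to cluster 5 (62.1 CPM), and chromosome 13 from 65 to 70 Mb lay at 0.491 of the way. Both places were picked after the mixture fit of the same barcodes, for differing between these clusters, so the positions are not separate support. Chance pairing at loading was argued against, since this pair made up 50.2% of barcodes mixed in both libraries, where cluster shares give 4.92%, or 8.43% when weighted for how readily each pair is found. Free RNA and DNA were also argued against, since mixed barcodes had 5.73 times the median UMIs of single ones. What brought these clusters together, for example clumps of cells or an uneven suspension, was not tested.

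Within clusters, the mitochondrial share may reflect how many barcodes kept their cytoplasm. In every cluster, barcodes at or over 2% had a higher share of ribosomal protein RNA than those under 2%, by at least 1.42-fold, while the nuclear RNAs MALAT1 and NEAT1 had ratios of 1.02, 0.662, 0.901, 0.985 and 0.707 in clusters 1 to 5. The barcodes at or over 2% also had 2.12 to 2.44 times the other UMIs. Their median peak counts were 0.723, 1.13, 0.693, 0.600 and 1.01 times those under 2%, and the lower counts in clusters 1, 3 and 4 were not explained. Free mitochondrial RNA was argued against, since the share rose with the other UMIs (median correlation of 0.464 over 5 clusters, -0.003 in cluster 1). With no cell filter at all, clustered anew at resolution 0.15, the lowest median of clusters 2, 4 and 5 was 15.6 times the highest of clusters 1 and 3. The low shares in clusters 1 and 3 thus remained with no 20% limit, but removal of that limit alone was not tested. Between clusters kept cytoplasm was not supported by nuclear RNA, which was lowest in clusters 1 and 3 (medians of 2.65% and 3.94% of the other UMIs, against 4.83%, 5.70% and 5.57% in clusters 2, 4 and 5), and differences between lines were not tested.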
